A study of Homo sapiens with 24 samples.

How the data were processed

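CUT&Tag libraries for H3K9me3, H3K4me3, H3K4me1 and H3K27ac were made from H9-derived ventricular-like cardiomyocytes at day 15, per the labels' protocols. Group, mark and replicate number came from the sample titles. The deposited files give raw read counts per region, not normalized, over a list of 153244 regions that is identical in all 24 libraries. The submitters' processing notes name Bowtie2 2.4.5, bedtools 2.30.0, deepTools 3.5.4 and the genome build hg19, without the role of each tool. How the regions were made and how reads were filtered is not given in the sources used here. Even counts made up between 51.9% and 65.9% of the counts above 0 in each library, an excess that would arise if both mates of a pair were counted. Intervals on counts may therefore be too narrow, and they cover counting error only. How the knockdown was made is not given in the sources used here.

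From the deposited counts, each mark was tested on its own 6 libraries with edgeR 4.0.16 (R 4.3.3). Regions with low counts were removed by filterByExpr, library sizes were scaled by TMM, and the quasi-likelihood test was run with robust estimation, with the group as the only term. Fold changes are knockdown over control, and regions with a Benjamini-Hochberg adjusted p under 0.05 were called. The filter left 30565 regions for H3K9me3, 26773 for H3K4me3, 85815 for H3K4me1 and 61484 for H3K27ac. The SE of a log2 fold change was taken as its size over the square root of the F statistic. CPM values use the TMM-scaled library sizes, and log2 CPM values use a prior count of 2. Principal components were computed on the 20% of tested regions with the highest mean log2 CPM. Positions count from 1. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No pair of libraries within a group had counts within sampling noise of each other (chi-square per degree of freedom 3.16 to 10.3), so none was merged as a library deposited more than once; counting both mates would raise this value too.

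A mark was taken as present where a region's mean control log2 CPM per kb (with 0.01 added) was in the top 20%. Regions with H3K4me3 were called promoter-like, other regions with H3K4me1 and H3K27ac enhancer-like, and other regions with H3K9me3 H3K9me3-marked. Named regions followed a rule fixed before the data were examined. Per mark, they are up to 10 higher and up to 10 lower regions with the smallest p among called regions whose 3 knockdown libraries lie on one side of the 3 control libraries. Where fewer than 5 pass, the 3 with the smallest p in each direction are named and said not to pass. A region within 10 kb of a named one is merged into it. Groups of neighbours within 100 kb, and the values of single regions outside this rule, were chosen after their values were seen. Between 14.4% and 17.5% of the tested regions of each mark had groups that did not overlap, where chance gives 10% for 3 against 3.

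The test was run on simulated counts with the means, dispersions and library sizes of each mark and 200 changed regions, of which those that passed the filter were counted. At a log2 fold of 1 these were 93 for H3K4me3, 92 for H3K9me3, 95 for H3K4me1 and 89 for H3K27ac, and at a log2 fold of 2 they were 90, 88, 93 and 82. At a log2 fold of 1, the share recovered was 51.6% for H3K4me3, 22.8% for H3K9me3, 6.32% for H3K4me1 and 3.37% for H3K27ac. At a log2 fold of 2 it was 80.0%, 76.1%, 59.1% and 40.2%. Unchanged regions called were 18, 4, 2 and 2. Doublings of H3K4me1 and H3K27ac were thus mostly not detected in this setting. The Benjamini-Hochberg cut is stricter when few regions change, so these shares reflect the 200 changed regions as well as depth and spread. In H3K4me3, the 18 unchanged regions were a larger share of all simulated calls than the adjusted p threshold allows. The share of false calls among the regions called in H3K4me3 may therefore also exceed that threshold.

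Alternatives fixed before the data were examined were RLE size factors, library totals alone, loess offsets on abundance (span 0.3), DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a strict filter (the CPM of 30 reads in the smallest library, in at least 3 libraries), a replicate block, leaving out each library, a minimum log2 fold change of 1, a top 10% cut for the chromatin classes and the use of all regions for correlations. Alternatives added later are named as such with their values. Tests of gene lists fixed in advance, cell type markers included, and the level of the targeted gene in each library need an hg19 annotation, which was not used here; the tests were not run, and the annotation table used here is of another build. The targeted gene therefore could not serve as a check of the labels.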

Results

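Histone marks were profiled by CUT&Tag, in which an antibody directs a transposase to cut and tag DNA at the marked nucleosomes, in ventricular-like cardiomyocytes derived from the human embryonic stem cell line H9. The cells were taken at day 15 of differentiation. Control cells were compared with cells in which ZNF436, a zinc finger protein gene, was knocked down. Each of 4 marks was measured in 3 control and 3 knockdown libraries, which gave 24 libraries. H3K9me3 is a mark of silenced heterochromatin, H3K4me3 of active promoters, H3K4me1 of enhancers and H3K27ac of active promoters and enhancers. All libraries were counted over the same 153244 regions (hg19), with a median width of 708 bp. The total count per library lay between 2103185 and 2880412 for H3K9me3, between 11023905 and 13933927 for H3K4me3, between 3920283 and 4936265 for H3K4me1 and between 2955710 and 3681687 for H3K27ac. Regions are given by position, since no gene annotation of this build was used. The series title concerns transposon-derived regulatory elements, and the comparisons ask where chromatin differed when ZNF436 was reduced.

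The smallest p of any mark belonged to a loss of H3K4me3 at a promoter-like region of chromosome 1 (positions 23686304 to 23698054). Whether this region is the promoter of ZNF436 itself was not checked, so the changes there may be those of the targeted gene. H3K4me3 there fell from 162 ± 9.74 normalised CPM (counts scaled to a common library size; SD, n = 3) in control cells to 10.4 ± 1.03 in knockdown cells. The log2 fold change was -3.96 (SE 0.10), with an adjusted p of 1.41e-14 in edgeR's quasi-likelihood test. H3K27ac fell in the same region from 115 ± 17.9 to 27.5 ± 6.43 CPM (log2 fold change -2.06, adjusted p = 0.00631, edgeR). H3K4me1 went from 33.4 ± 5.93 to 12.5 ± 6.91 CPM, which did not pass the test (adjusted p = 0.105, edgeR). H3K9me3 was 151 ± 19.1 CPM in control and 249 ± 18.0 CPM in knockdown cells, also short of the threshold (log2 fold change 0.73, adjusted p = 0.0648, edgeR). Directly beside it, at positions 23699122 to 23700480, H3K9me3 rose from 3 counts over the control libraries to 77 over the knockdown libraries. That is a ratio of 26.0 with a 95% exact interval of 8.58 to 129, which covers counting error only (adjusted p = 0.0047, edgeR). On the other side, at positions 23684326 to 23685857, H3K9me3 was lower in knockdown cells, 23.0 ± 8.77 against 13.1 ± 0.48 CPM, and did not pass (log2 fold change -0.80, unadjusted p = 0.0366, adjusted p = 0.575, edgeR).

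**Figure D1:**
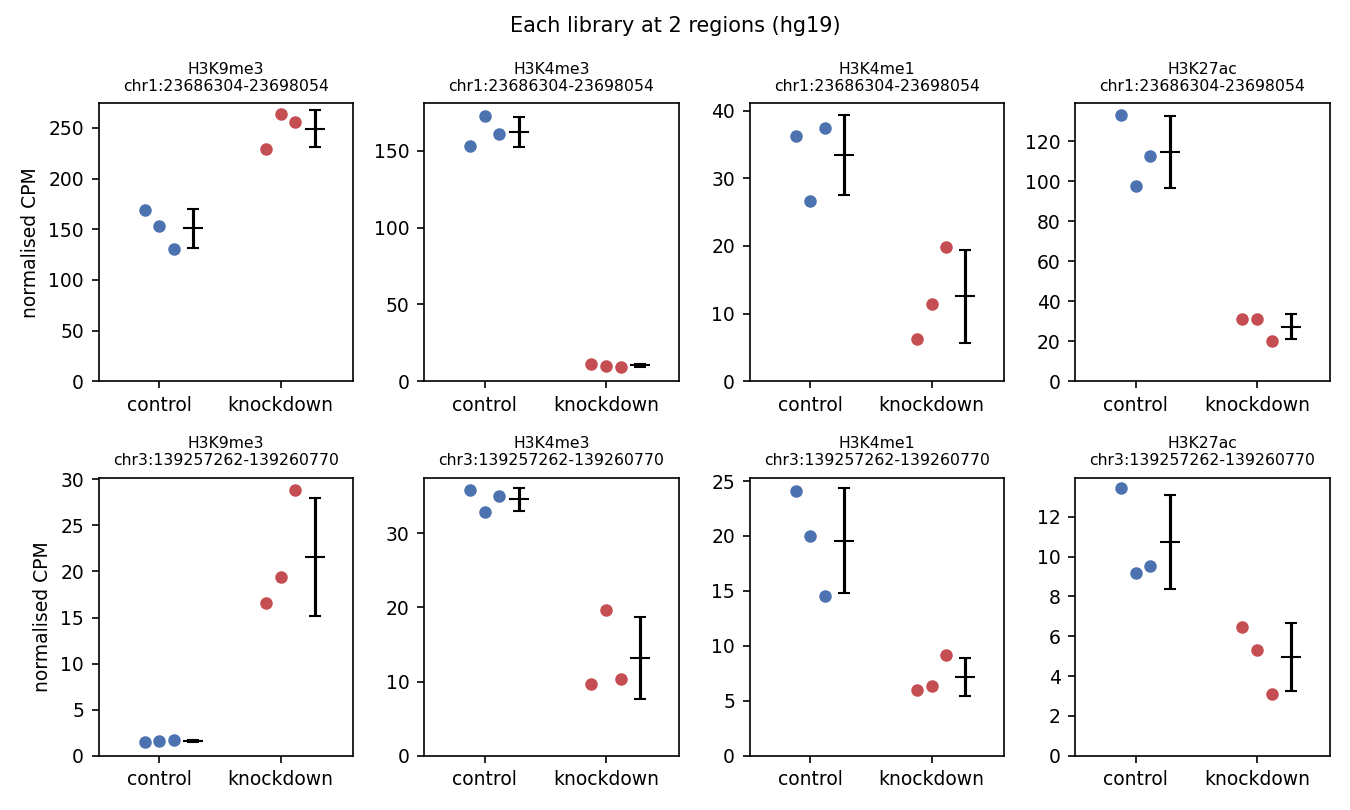
Normalised CPM (vertical axis, starting at 0) of each library for the 4 marks at a region of chromosome 1 (top) and one of chromosome 3 (bottom), with points for libraries and black bars for the mean and SD of 3. In both regions the H3K4me3 values of the knockdown libraries lie below those of every control library, and the H3K9me3 values lie above them.

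Few H3K9me3 regions passed the test with all libraries. Of 30565 regions tested, 2 were higher and 1 was lower in knockdown cells (edgeR, adjusted p under 0.05). The second region that rose, on chromosome 3 (139257262 to 139260770), was promoter-like and went from 1.59 ± 0.15 to 21.6 ± 6.40 CPM (SD, n = 3; log2 fold change 3.71, SE 0.56, adjusted p = 0.000136, edgeR). H3K4me3 fell in that region from 34.6 ± 1.5 to 13.2 ± 5.57 CPM (adjusted p = 0.0196, edgeR). The values of H3K4me1 (19.6 ± 4.80 and 7.15 ± 1.73 CPM) and H3K27ac (10.7 ± 2.36 and 4.95 ± 1.72 CPM) there did not pass the test. The region that lost H3K9me3, on chromosome 13 (96490704 to 96493251), went from 33.8 ± 6.20 to 6.38 ± 2.63 CPM (log2 fold change -2.38, adjusted p = 0.000496, edgeR), and too few counts of the other marks were present there for a test. By the naming rule, 3 regions that did not pass are also given. These lay on chromosome 1 (16949693 to 16954510, log2 fold change 1.86, adjusted p = 0.0579), chromosome 8 (99753172 to 99758887, -1.06, adjusted p = 0.119) and chromosome 9 (99513376 to 99531004, -0.62, adjusted p = 0.133). Across the regions tested, 2541 had an unadjusted p under 0.05. DESeq2 gave 3 higher and 46 lower regions, and its filter on low counts left all 3 edgeR calls without an adjusted p. In edgeR, the 3 calls became 20 without control replicate 2, 15 without control replicate 3, 5 without control replicate 1, and 10 and 8 without knockdown replicates 2 and 3.

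H3K4me3 was higher at 100 and lower at 50 of 26773 tested regions. The median size of the change was 0.95 on the log2 scale for the higher and 0.95 for the lower regions. At least a doubling was seen at 44 of the higher regions, and at least a halving at 23 of the lower ones. Among the higher regions, 20 had under 5 CPM in control cells and 28 had over 50 CPM. The smallest p among the higher regions belonged to chromosome 6 (127437365 to 127444343), where H3K4me3 rose from 79.0 ± 4.05 to 185 ± 16.1 CPM (log2 fold change 1.23, SE 0.07, adjusted p = 4.67e-08, edgeR). H3K4me3 rose from 24.6 ± 4.06 to 67.1 ± 3.36 CPM on chromosome 19 (7980530 to 7983265) and from 11.6 ± 2.42 to 34.4 ± 2.3 CPM on chromosome 1 (28198573 to 28200243). On chromosome 18, regions with little H3K4me3 in control cells gained it. The first (44789051 to 44790857) went from 2.24 ± 0.92 to 15.1 ± 2.91 CPM, and the second (56216374 to 56219317) from 1.47 ± 0.28 to 9.32 ± 2.46 CPM. The other named regions that rose lay on chromosome 12 (122229546 to 122233775, log2 fold change 0.98), chromosome 3 (127390412 to 127393184, 0.78), chromosome 19 (916733 to 920901, 1.18), chromosome 1 (2474371 to 2479975, 1.47) and chromosome 8 (25900236 to 25904639, 1.19).

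After the chromosome 1 region, the smallest p among regions that lost H3K4me3 was on chromosome 17 (46679187 to 46680541), which went from 7.51 ± 2.50 to 0.93 ± 0.24 CPM (log2 fold change -3.00, SE 0.39, adjusted p = 0.0012, edgeR). On chromosome 10, a region at 105435532 to 105438712 went from 7.91 ± 2.44 to 1.27 ± 0.18 CPM. Smaller losses at strongly marked promoter-like regions included chromosome 2 (54784590 to 54788847), from 140 ± 6.36 to 98.0 ± 3.97 CPM, and chromosome 10 (88122439 to 88127696), from 79.0 ± 9.52 to 41.9 ± 6.95 CPM. The log2 fold change was -0.65 on chromosome X (130961846 to 130965839), -0.62 on chromosome 20 (14313235 to 14318582), -0.62 in another region of chromosome 10 (5488202 to 5492280), -2.23 on chromosome 18 (53067819 to 53070686) and -1.81 on chromosome 5 (169930701 to 169932473). Of the 150 changed regions, 13 lay in 6 groups of neighbours within 100 kb, and all 6 groups moved in a single direction. The largest such group held 3 regions on chromosome 4 (151499859 to 151510335), all lower. Single libraries moved these counts. Without control replicate 3, 515 regions were higher and 290 lower, while without knockdown replicate 3 the counts were 20 and 7; leaving out any other library gave totals between 43 and 240.

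**Figure D2:**
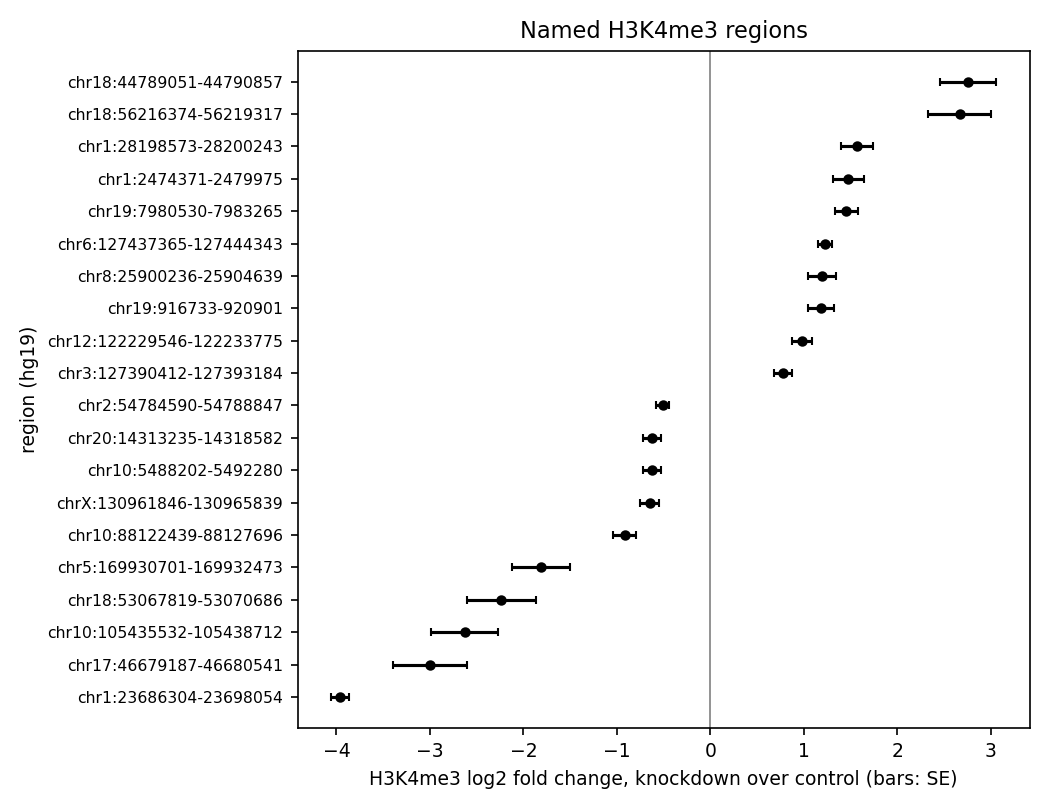
H3K4me3 log2 fold change of knockdown over control (horizontal axis) for the 20 regions named by rule (vertical axis, hg19 positions), with points for the edgeR estimate and bars for its SE. Among these 20, the largest loss is -3.96 at the chromosome 1 region, and the largest gain is 2.75 on chromosome 18.

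H3K27ac rose at 5 regions and fell at 2 of 61484 tested. The chromosome 6 region that gained H3K4me3 (127437365 to 127444343) also gained H3K27ac, from 15.9 ± 8.47 to 84.7 ± 12.4 CPM (log2 fold change 2.41, SE 0.33, adjusted p = 0.00957, edgeR). H3K27ac also rose on chromosome 3 (75550641 to 75556745), from 19.4 ± 8.01 to 80.5 ± 20.3 CPM, on chromosome 8 (118181606 to 118186908), from 27.5 ± 9.66 to 91.2 ± 12.6 CPM, and at a second site of chromosome 6 (126351042 to 126352611), from 5.05 ± 0.87 to 31.6 ± 7.08 CPM. A short region of chromosome 16 (50180312 to 50180939) held 2 counts over the control libraries and 125 over the knockdown libraries, a ratio of 59.1 (95% exact interval 16.0 to 494, counting error only). Besides the chromosome 1 region, H3K27ac fell on chromosome 4 (151499859 to 151506019), from 59.5 ± 29.9 to 11.3 ± 2.69 CPM (log2 fold change -2.39, adjusted p = 0.0367, edgeR), and H3K4me3 fell there as well (-0.98, adjusted p = 0.0142). These 7 calls dropped to 0 without control replicate 1 and without knockdown replicate 1, 2 or 3, and became 92 without control replicate 2 and 1412 without control replicate 3; DESeq2 called 669 and limma-voom 185.

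H3K4me1 gave 0 changed regions among 85815 tested in edgeR, with a smallest adjusted p of 0.0649. At an unadjusted p under 0.05 there were 9003 regions, while DESeq2 called 94 and limma-voom 67. Named by rule without passing the test, the regions with the smallest p and higher H3K4me1 lay on chromosome 20 (16694379 to 16695728, log2 fold change 1.92), chromosome 5 (87390006 to 87390797, 3.06) and chromosome 8 (12402662 to 12405534, 2.37). Those with lower values lay on chromosome 4 (8504240 to 8505277, -2.10), chromosome 12 (48373251 to 48374344, -2.87) and chromosome 1 (23699122 to 23700480, -2.3). The last is the site that gained H3K9me3. Without control replicate 3, edgeR called 1453 higher and 990 lower regions, and without control replicate 2 it called 243.

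Regions whose H3K4me3 changed mostly had H3K27ac values on the same side. Of the 150, 128 could be tested in H3K27ac, and 111 had a log2 fold change of the same sign. At an unadjusted p under 0.05 in H3K27ac, 45 had the same sign and 0 the opposite. Of the higher regions, 84.7% were higher in H3K27ac, and of the lower regions 90.7% were lower. Other divisions of the H3K27ac libraries into 3 and 3 reached 83.5% and 86.0% on one side, so these shares exceeded those from regrouped libraries by little. Each other division still sets most of one group against most of the other. It therefore does not show the share expected without a difference, and the comparison decides nothing. In H3K4me1, 47 of 98 regions with more H3K4me3 were higher and 51 lower, and of 48 regions with less H3K4me3, 16 were higher and 32 lower. Across regions tested in both marks, Spearman's rho of the log2 fold changes was 0.33 between H3K4me3 and H3K27ac, 0.39 between H3K4me1 and H3K27ac and 0.17 between H3K4me3 and H3K4me1. The highest values over the other 9 divisions of the libraries were 0.31, 0.39 and 0.21. Within the control group, control 3 minus control 2 correlated between these pairs of marks at 0.28, 0.39 and 0.21 (Pearson). For knockdown 3 minus knockdown 2 the values were 0.03, 0.02 and 0.02. Agreement between marks of about this size thus also arose between control replicates 2 and 3, without the knockdown. Among the controls, these lay furthest apart on the first principal component of each of these marks. Other pairs of controls were not compared between marks in this way. Against H3K9me3, rho was -0.20 for H3K4me1, -0.09 for H3K4me3 and -0.03 for H3K27ac, where the same other divisions of both marks reached absolute values of 0.13, 0.04 and 0.09. Combinations of different divisions of the marks reached 0.21, 0.10 and 0.16, above the observed sizes. These correlations are across regions, which are not independent replicates.

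**Figure D3:**
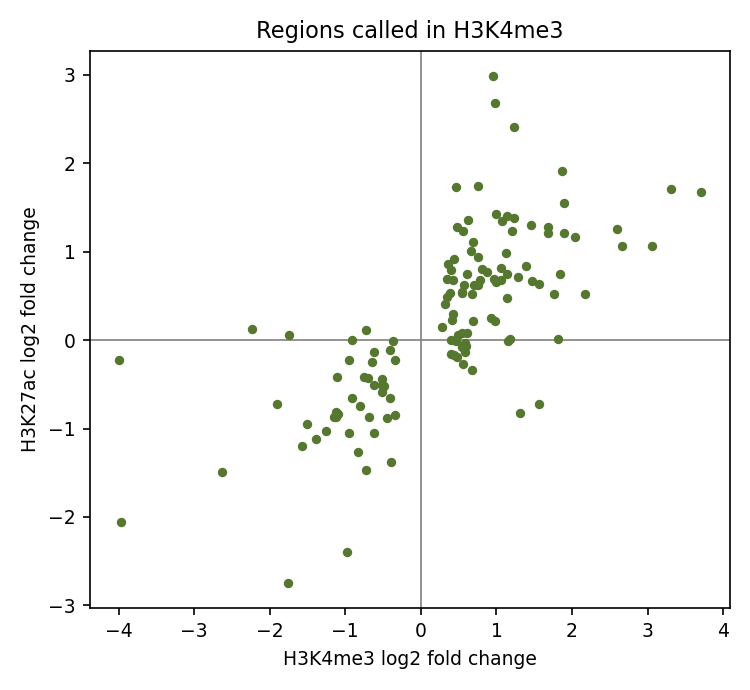
Log2 fold change of H3K27ac (vertical axis) against that of H3K4me3 (horizontal axis) at the 128 regions called in H3K4me3 and tested in both marks, with a point for each region and grey lines at 0. Most points, 111 of them, lie where both marks moved to the same side.

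Most changed H3K4me3 regions were promoter-like, meaning that they were among the 20% of regions with the most H3K4me3 in control cells. Of the 150, 144 were promoter-like (94 higher and 50 lower), against 23597 of the 26773 tested. Enhancer-like regions, with high H3K4me1 and H3K27ac, held 1 call among 1314 tested. With a 10% cut, 107 of the 150 were promoter-like, and enhancer-like regions held 7 calls among 1989. The classes are set on H3K4me3 in the same control libraries, and changes are easier to call where counts are high, so these shares are partly built in and no enrichment is claimed. The median log2 fold change at enhancer-like regions was -0.19 for H3K4me1 and -0.31 for H3K27ac, and that of H3K9me3 at H3K9me3-marked regions was -0.11. Other divisions of the libraries reached absolute values of 0.085, 0.105 and 0.072. Only the real division has all the libraries that set the classes on one side, so larger values there do not show a loss. Medians above 0 included those of H3K9me3 at promoter-like (0.39), enhancer-like (0.65) and other regions (0.57) and of H3K4me1 at H3K9me3-marked regions (0.54), where other divisions of the libraries reached absolute values of 0.47, 0.59, 0.28 and 0.44. These cover only the regions with enough counts over all libraries (3547 of 30649, 267 of 7562, 4566 of 84936 and 1014 of 30097). The class of other regions, and in part the H3K9me3-marked class for H3K4me1, leaves out regions high in the mark in control cells. Regions low in control cells can pass the filter through high knockdown counts, which raises these medians, so they do not show a gain. Promoter-like and enhancer-like classes were not set on H3K9me3, so this does not account for their medians. At an unadjusted p under 0.05 (edgeR), 351 promoter-like regions were higher in H3K9me3 and 43 lower, and 36 enhancer-like regions were higher and 0 lower. The cause was not tested, and no gain is claimed. The control libraries that set the classes also enter the fold changes, which lowers the values of regions picked for high control signal. With the class set on a single control library and the fold taken against the other controls, the enhancer-like medians for libraries 1, 2 and 3 were -0.13, -0.060 and 0.10 for H3K4me1 and -0.15, -0.077 and 0.24 for H3K27ac.

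By chromosome, no share of changed H3K4me3 regions differed from the share tested (Fisher's exact test, smallest Benjamini-Hochberg adjusted p = 0.514). Chromosome 19, which holds large clusters of zinc finger genes, had 15 changed regions where 9.61 would be expected, and 15 were higher and 0 lower. Whether these 15 lie in such clusters was not tested.

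The groups overlapped on the first principal component in H3K4me3 and H3K4me1 and did not overlap in H3K9me3 and H3K27ac. Spearman correlations of log2 CPM between libraries of one group ranged from 0.96 to 0.97 for H3K4me3, from 0.73 to 0.81 for H3K9me3, from 0.65 to 0.82 for H3K4me1 and from 0.61 to 0.76 for H3K27ac. Between groups the ranges were 0.95 to 0.97, 0.71 to 0.80, 0.66 to 0.80 and 0.60 to 0.71. On this component of H3K27ac, control replicates 1 and 2 scored -27.9 and -59.3, control replicate 3 scored 12.2, and the knockdown libraries scored 30.2, 16.6 and 28.2. Control replicate 3 also lay on the knockdown side in H3K4me3 (3.37) and H3K4me1 (19.5), and on the control side in H3K9me3 (-2.94). The mean scores of the groups did not pass a test (exact permutation test, two-sided, p = 0.1 for H3K9me3 and H3K27ac and 0.2 for H3K4me3 and H3K4me1, n = 3; 0.1 is the smallest p possible). The 1% of regions with the most counts held 49.0% ± 2.72 of the H3K9me3 counts in control and 47.8% ± 1.81 in knockdown libraries (SD, n = 3). The shares were 25.6% ± 0.38 and 25.7% ± 0.18 in H3K4me3, and 14.3% ± 0.40 and 13.5% ± 0.51 in H3K4me1. In H3K27ac they were 17.4% ± 1.41 and 19.2% ± 0.30, and there the groups did not overlap (exact permutation test, p = 0.1). In H3K4me1 the groups did not overlap in the share of regions without counts, 23.8% ± 1.40 in control and 20.6% ± 1.16 in knockdown libraries. They also did not overlap there in the share of counts in the 100 regions with the highest mean control CPM over all marks, 1.48% ± 0.35 and 2.12% ± 0.21 (exact permutation test, p = 0.1 for each). In the other marks the groups overlapped in both.

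**Figure D4:**
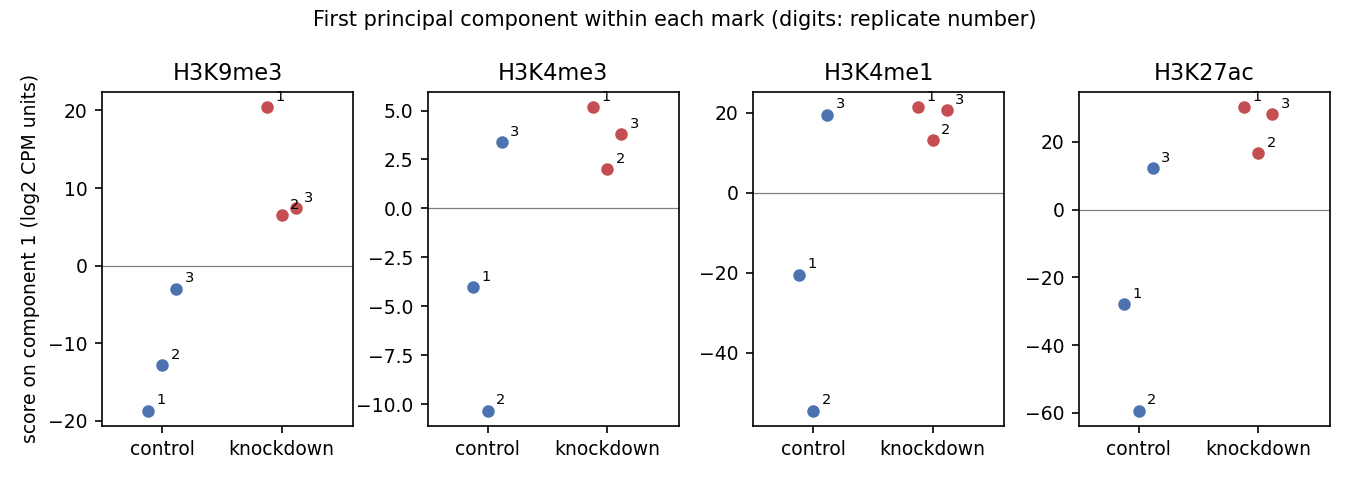
Score of each library on the first principal component of its mark (vertical axis, log2 CPM units) for control and knockdown libraries, with digits for replicate numbers and a grey line at 0. Control replicate 3 lies above 0 with the knockdown libraries in H3K4me3, H3K4me1 and H3K27ac, and below 0 in H3K9me3.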

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

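The alternatives named here as added (halved counts, leaving out the 100 highest regions, and chromatin classes set on a single control library) were chosen after seeing the data. For the 39 named regions, 652 values under other settings were compared, and 0 changed sign. Of these values, 553 stayed on their side of the threshold, 47 lost it and 52 gained it. The 39 were picked for the smallest p in the same libraries, and in each the control and knockdown libraries did not overlap. A change of sign was thus unlikely by the choice itself, and its absence is no separate evidence. The cause of the differences below was not tested. H3K4me3 counts of 150 became 456 with DESeq2, 666 without a filter (352 higher, 314 lower) and 67 with a minimum fold, while leaving out a library gave 27 to 805, the highest without control replicate 3 and the lowest without knockdown replicate 3. Without control replicates 1 and 2 the counts were 63 and 240, and without knockdown replicates 1 and 2 they were 43 and 81. The 3 H3K9me3 calls became 5 with loess offsets, 49 with DESeq2, 6 with limma-voom and 5 without the 100 highest regions. Leaving out a library gave 4 to 20, the highest without control replicate 2, and 15 without control replicate 3, 10 and 8 without knockdown replicates 2 and 3, and 5 without control replicate 1. The 0 H3K4me1 calls became 10 (10 higher, 0 lower) with library totals alone, 94 with DESeq2, 67 with limma-voom and 208 without a filter, and leaving out a library gave 0 to 2443, the highest without control replicate 3 and 243 without control replicate 2. The 7 H3K27ac calls became 4 (2 higher, 2 lower) with library totals, 12 (6 higher, 6 lower) with loess offsets, 669 with DESeq2, 185 with limma-voom, 599 without a filter, 43 with the strict filter, 118 with halved counts and 17 without the 100 highest regions, and leaving out a library gave 0 to 1412, the highest without control replicate 3.

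Same-numbered control and knockdown libraries had correlations of deviations from -0.10 to 0.06, and differently numbered ones from -0.08 to 0.10. These values showed no pairing by replicate number, but with 3 libraries per group they cannot exclude it. With a replicate block the counts were 6 for H3K9me3, 177 for H3K4me3, 94 for H3K4me1 and 102 for H3K27ac, and with the block and without the 100 highest regions they were 6, 189, 80 and 134. The block moved no correlation between marks by more than the spread over other divisions of the libraries. Over all regions, in place of those tested in both marks, rho was -0.0084 for H3K9me3 with H3K4me3, -0.028 for H3K9me3 with H3K4me1, 0.12 for H3K4me3 with H3K4me1, 0.12 for H3K4me3 with H3K27ac and 0.23 for H3K4me1 with H3K27ac, and for H3K9me3 with H3K27ac it turned from -0.0288 to 0.00652, within the spread over other divisions. With the top 10% cut, calls among promoter-like regions went from 144 to 107 and those among enhancer-like regions from 1 to 7, counts that the choice of class partly fixes. The median log2 fold change with this cut was -0.21 for H3K9me3 at H3K9me3-marked, -0.00901 for H3K4me3 at promoter-like and -0.20 for H3K27ac at enhancer-like regions. With the class set on control 1, 2 or 3 alone, these medians were -0.0679, -0.0898 and -0.0483 for H3K9me3, -0.0103, -0.00691 and -0.0107 for H3K4me3, -0.154, -0.0772 and 0.237 for H3K27ac, and -0.134, -0.0605 and 0.10 for H3K4me1 at enhancer-like regions, so the last 2 marks turned sign with control 3. The median of H3K9me3 at other regions went from 0.57 to 0.217 with the top 10% cut. With the class set on control 1, 2 or 3 alone it was 0.129, 0.0922 and 0.0931. At promoter-like regions it went from 0.39 to 0.294, 0.505 and 0.220, and at enhancer-like regions from 0.65 to 0.517, 0.722 and 0.601. The filter on all libraries can raise the median of the class of other regions in each of these settings. The median of H3K4me1 at H3K9me3-marked regions went from 0.54 to 0.277 on control 1 and 0.734 on control 3. On chromosome 19, the 15 calls with loess offsets were the same 15 regions. The alternatives for gene lists were not run, and that for normalized values did not apply to counts.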

Other observations

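The tests of explanations for the patterns, those at the chromosome 1 region, between libraries and on chromosome 19, the test of higher regions alone there, and the counts over regrouped libraries were chosen after the results they bear on had been seen, and the patterns were found in the same data. Besides the regions already named, changed H3K4me3 regions formed pairs of neighbours that rose on chromosome 1 (89663378 to 89667387, log2 fold changes 1.07 and 1.90), chromosome 10 (103534651 to 103604279, 1.29 and 2.60) and chromosome 16 (724319 to 778962, 0.76 and 1.56). On chromosome 6 the region beside the one that gained both active marks (127445128 to 127445689) rose in H3K4me3 by a log2 fold change of 2.73 (adjusted p = 0.0130, edgeR). The only pair that fell was on chromosome 17 (46673343 to 46680541, -2.18 and -3.00). These groups were chosen after their values were seen.

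The first pattern is the chromosome 1 region that lost H3K4me3 and H3K27ac. Loss of DNA or of mappable sequence over the whole region would lower every mark. H3K9me3 there had a log2 fold change of 0.73 (SE 0.15), above 0 by more than 2 SE, though short of the threshold (adjusted p = 0.0648, edgeR). This argues against loss of the whole region. The region is 11751 bp wide, and the marks may lie in different parts of it. Loss of only a part of it therefore cannot be tested with these counts. Silencing with H3K9me3 gain and H3K4me3 loss at the same loci stays open as a hypothesis. Both regions that gained H3K9me3 lay within 10 kb of a region that lost H3K4me3, as did 17 of the 30565 tested (exact hypergeometric test, p = 2.91e-07), but 1 of the 2 is the site that prompted the test, so this p largely restates the pattern. A candidate explanation is that the region, with its H3K4me3 log2 fold change of -3.96, is the promoter of the knocked-down gene. This was not checked, because no hg19 annotation was used, though such an annotation would show whether the promoter lies there. The way the knockdown was made is not given in the sources used here. A direct effect of it on the region was therefore not told apart from an indirect one.

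The second pattern is that control replicate 3 lies beside the knockdown libraries in H3K4me3, H3K4me1 and H3K27ac. At the chromosome 1 region, its level was 0.99, 1.19 and 0.976 times the mean of the other controls in the 3 marks in this order. The highest single knockdown library was 0.071, 0.63 and 0.27 times that mean. The region was picked for its H3K4me3 p with control replicate 3 counted as a control, which partly fixes the H3K4me3 value. The H3K4me1 and H3K27ac values did not enter that choice, and in those marks they argue against a knockdown library labelled as a control. In disjoint libraries, control 3 minus control 2 correlated across regions with the knockdown mean minus control 1 at 0.17 in each of the 3 marks and 0.00 in H3K9me3, and control 3 minus control 1 correlated with the knockdown mean minus control 2 at 0.24 in H3K4me3, 0.33 in H3K4me1, 0.23 in H3K27ac and 0.10 in H3K9me3. A loess trend on abundance carried at most 0.015 of the variance of either difference in the 3 marks with control 1 as reference, and its removal left the lowest of the 3 values at 0.165, which argues against such a trend as the whole cause. The values are consistent with a difference between control preparations that runs along the knockdown difference, though control 1 minus control 2 against the knockdown mean minus control 3 gave -0.073, -0.18 and -0.070 in the 3 marks and -0.097 in H3K9me3, in H3K4me1 as large as the 0.17, and whether that difference is biological was not tested.

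The third pattern is that 15 H3K4me3 regions were higher and 0 lower on chromosome 19 (Fisher's exact test for higher regions, Benjamini-Hochberg adjusted p = 0.0416; the test of both directions fixed in advance gave 0.514). An extra copy of the chromosome in all cells would raise all its regions, but the median log2 fold change of those tested was 0.0371, which argues against it. Of the chromosomes other than Y, this one had the highest median in H3K4me3, in H3K4me1 (0.088) and in H3K27ac (0.032). An abundance trend between the libraries is argued against as the whole cause, since loess offsets moved the log2 fold changes of H3K4me3 regions by up to 0.42 but those of the 15 by at most 0.0218, where the smallest of the 15 was 0.34 and their smallest SE 0.064, and the same 15 were called. An effect of the knockdown on this chromosome stays open as a hypothesis, and no biological explanation was tested.

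With 3 libraries against 3 there are 10 divisions of the 6 libraries, too few for a share under 0.05. The real division gave 3 calls in H3K9me3, 150 in H3K4me3, 0 in H3K4me1 and 7 in H3K27ac, and the highest of the other 9 gave 0 in each mark. Every other division mixes both groups on each side. A region that differs between the groups then varies within each side and is hard to call. The 0 calls are therefore partly built in, and the comparison decides nothing. The number of divisions with as many calls, the real one included, was 1, 1, 10 and 1. At an unadjusted p under 0.05, the real division gave 2541, 2726, 9003 and 6919 regions in the same order, and the highest other gave 1625, 2029, 8244 and 4592. In every mark that other division set control replicates 1 and 2 with knockdown replicate 2 against the rest.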
